A study of Mus musculus with 10 samples.

How the data were processed

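Bulk RNA sequencing was done on cells sorted as CD8+ T cells from MC38 tumours of 10 mice, 5 WT and 5 S452A, per the labels. Per the labels' protocols, RNA was extracted with a micro-scale column kit and directional libraries were made from 40 ng of RNA. Per the submitters' processing notes, STAR 2.7.9a and RSEM 1.3.0 were used with the mouse genome build GRCm38.p6. The annotation release and the parameters of these tools are not given in the sources used here. The authors deposited 1 table of TPM values, which are already scaled to gene length and to a fixed total per library. Each column summed to 1000000 within rounding. TPM keeps no counts, so the depth of each library is unknown, no counting interval can be given, and a lower abundance of one class of transcripts raises the TPM of the others. A gene listed at 0 is given as such, without a fold change.

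Columns were matched to samples through the sample descriptions, and groups came from the genotype labels. The labels number separate mice 1 to 5 in each genotype, so p-values for single genes and single measures are set against the spread between mice. The list test at a preset correlation, described below, compares a list's genes with other genes, and its p-values do not measure that spread. The design, the gene lists, the rule for named genes and the main alternatives were chosen before the data were examined. Of 55487 gene rows, 55094 matched GENCODE mouse release M21 (GRCm38) by versioned identifier and 55394 without the version, and 111 rows share a symbol with another row and were kept separate. Gene positions and the mutated codon of Ptpn22 came from that annotation. Near-identical copies of named genes were searched among its transcripts with blastn 2.17.0 (at least 95% identity over at least 0.8 of the shorter transcript).

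Genes with at least 1 TPM in at least 5 libraries were tested (13930 genes, 99.6% of the TPM). Values were analysed as log2(TPM + 1), with a pseudocount of 1, in R 4.3.3 with limma 3.58.1 (lmFit and eBayes with a trend, 2-sided, Benjamini-Hochberg adjusted p under 0.05), with genotype as the only term. Differences are S452A minus WT on this scale, which understates the change of low genes, and intervals are at 95%. Gene lists with at least 5 tested members were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, with fry, which asks whether a list's genes move on balance one way and does not compare them with other genes, and by exact permutation of list means. Of 35 lists, 33 were tested. The gamma delta and innate-like T cell list and the list of Y-linked genes and Xist each had 1 gene above the filter, too few to test. Single measures were compared with 2-sided exact permutation tests, whose smallest possible p is 0.00794 with 5 against 5. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used for the rest.

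The text names Ptpn22 and 25 other T cell genes fixed in advance, whether or not they passed. It also names up to 10 genes in each direction that passed or, where fewer did, those that passed with the 5 of smallest unadjusted p, leaving out predicted and clone-named genes. For each list that passed, the 4 members of smallest unadjusted p are named. Gm36079 falls outside this rule as a predicted gene and is named because it was the only gene that passed. Macrophage and other marker genes were picked for display from lists fixed in advance after their values were seen.

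The fit was tested on simulated data for the S452A against WT comparison, with 13930 genes, 20 simulations and 200 shifted genes. It recovered 62.75% of genes shifted by 1 on the log2 scale and 93.4% of those shifted by 2, with 5.45% of calls false, and with no effect it called 0.05 genes on average. A proliferation list shifted by 0.5 was found in 20 of 20 simulations. All genes were drawn independently, whereas the estimated correlation within this list was 0.554 in the real libraries. Other splits of the real libraries gave a median of 11 lists past the threshold, so the rates of the simulation need not hold for these data.

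Alternatives were pseudocounts of 0.1 and 5, leaving out each library, the mouse number as a block, rescaling by the median log ratio, quantile normalization, rescaling without mitochondrially encoded, histone, immunoglobulin and small RNA genes, other filters, robust moderation, sample quality weights, the macrophage list mean as a covariate, a threshold of 0.1, an exact Wilcoxon rank-sum test, and the other list tests. After the data were seen, the mean of 8 T cell genes as a covariate and the summing of near-identical copies were added. Of the 126 possible splits of the 10 libraries into 5 and 5, 100 were drawn, the real one included.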

Results

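The series addressed the role of a serine (Ser452) of Ptpn22, the gene of the protein tyrosine phosphatase Pep, in CD8+ T cells that infiltrate a tumour. Mice with the wild-type gene (WT) and mice in which this serine is replaced by alanine (S452A) received MC38 cells, a mouse colon carcinoma line, at 8 weeks of age. Tumours were taken after 18 days and digested with collagenase, and CD8+ T cells were sorted for bulk RNA sequencing. The design text of the series writes the change as S425A where the title and the sample labels write S452A, and the latter is used here. There were 10 libraries, 5 per genotype, each labelled as a separate mouse. The deposited table gave TPM (transcript abundance scaled to a fixed total per library) for 55487 annotated genes, of which 13677 to 14388 reached 1 TPM in a library. TPM keeps no sequencing depth, so the depth is unknown and no detection floor is given. Pairwise correlations of the libraries across genes, which are not independent replicates, were 0.936 to 0.969, and no library was a copy of another.

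The libraries labelled CD8+ T cells held few T cell transcripts and abundant macrophage transcripts, in both genotypes. Cd8a, a chain of the CD8 coreceptor, was at 6.20 ± 5.49 TPM (SD, n = 5) in WT and 6.50 ± 5.46 in S452A. Cd3e, a chain of the T cell receptor complex, was at 3.25 ± 2.49 and 2.58 ± 1.93 TPM, and Trac, the constant region of the receptor's alpha chain, at 9.18 ± 6.12 and 6.77 ± 5.20 TPM. Apoe, an apolipoprotein made by macrophages, was at 10587 ± 1976 TPM in WT and 10641 ± 1361 in S452A. C1qb, a chain of complement C1q, was at 2902 ± 562 and 2498 ± 358 TPM. Cd14, a lipopolysaccharide coreceptor of monocytes and macrophages, was at 1854 ± 272 and 2304 ± 617 TPM, and Csf1r, the receptor for macrophage colony-stimulating factor, at 165 ± 22.2 and 167 ± 31.6 TPM. These macrophage genes are members of a list fixed in advance, and they were picked from it for display after their values were seen.

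**Figure D1:**
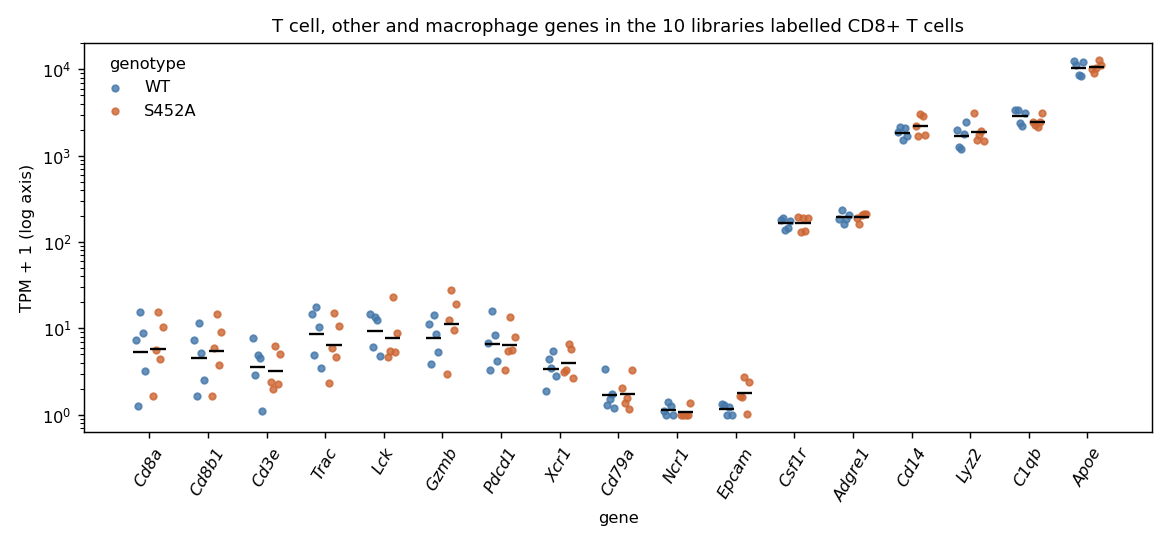
TPM plus 1 on a log axis for 17 genes in the 5 WT and 5 S452A libraries, 1 point per library, with a black line at the mean of the log values. Cd8a lies between 0.27 and 14.5 TPM, whereas Apoe lies between 8290 and 12719 TPM.

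Of the 36 genes of the macrophage and monocyte list, 29 averaged at least 100 TPM, and their mean log2(TPM + 1) was 8.12 ± 0.11 in WT and 8.17 ± 0.13 in S452A (SD, n = 5). The 18 tested genes of the CD8 T cell identity list averaged 2.59 ± 0.84 and 2.61 ± 0.82. Among the 13930 tested genes, 8 T cell genes (Cd3d, Cd3e, Cd3g, Trac, Trbc1, Trbc2, Cd8a and Cd8b1) had a median percentile of 6.77 to 55.4 per library. The median percentile of 8 macrophage genes (C1qa, C1qb, Csf1r, Adgre1, Cd68, Lyz2, Cd14 and Apoe) was 99.0 to 99.4. The tests on these sets of 8 were chosen after values were seen. The 8 macrophage genes averaged 10.2 as log2(TPM + 1) in WT, above the 8.12 of their whole list. The gap between the sets of 8 is therefore wider than that between the fixed lists. The macrophage genes lay 6.08 to 9.23 above the T cell genes on the log2 scale in each of the 10 libraries. This gap differed between genotypes by less than the spread between mice (7.63 ± 1.29 in WT, 7.59 ± 1.08 in S452A, SD, n = 5, 2-sided exact permutation p = 0.952). Some genes of other cell types also lay above the T cell genes. The fibroblast genes Col3a1 and Postn were at 47.0 ± 19.5 and 38.4 ± 8.46 TPM in WT and 29.3 ± 12.5 and 24.2 ± 6.43 TPM in S452A (SD, n = 5). Of the lists for other cells, 5 dendritic cell genes, 3 neutrophil genes, 2 natural killer cell genes, 1 fibroblast and pericyte gene and 1 CD4 and regulatory T cell gene averaged at least 100 TPM. These include the MHC class II gene H2-Aa (665 ± 127 TPM in WT), Il1b (3134 ± 537) and the signalling adaptor gene Tyrobp (1017 ± 76.9), which macrophages also express. The 6 tested genes of the B and plasma cell list averaged 3.59 ± 0.50 in WT and 3.31 ± 0.65 in S452A as log2(TPM + 1) (SD, n = 5), above the CD8 T cell identity list. Only these 6 of its 19 genes passed the expression filter, against 18 of 20 for CD8 T cell identity. The means of these lists therefore do not rank the 2 cell types. Among narrower markers, Xcr1 and Clec9a of type 1 dendritic cells reached at most 5.52 and 1.64 TPM, Cd79a of B cells 2.37, Ncr1 of natural killer cells 0.41, Epcam of epithelial cells 1.74 and S100a8 of neutrophils 14.1 TPM, all picked after their values were seen. Every comparison of genotypes that follows is therefore a comparison of libraries with this content.

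The level of Ptpn22 itself did not pass the test between genotypes. Ptpn22 (ENSMUSG00000027843) lies on the plus strand of chromosome 3, from 103859795 to 103912247 in GRCm38, and the codon of Ser452 in its main transcript falls in exon 13 of 21, at 103885888 to 103885890. Ptpn22 was at 14.7 ± 3.82 TPM in WT and 18.1 ± 4.84 TPM in S452A (SD, n = 5). The log2 difference, S452A minus WT, was 0.29 (SE 0.21, 95% interval -0.17 to 0.75, limma adjusted p = 0.952), and the exact permutation p was 0.238. A change of 1 codon need not alter the level of a transcript, and the table holds no reads, so the genotype of a library could not be checked from it.

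None of the T cell genes named in advance passed the test between genotypes. Gzmb, encoding the cytotoxic protease granzyme B, was at 7.64 ± 4.22 TPM in WT and 13.4 ± 9.50 in S452A (SD, n = 5), a log2 difference of 0.55 (SE 0.54, limma adjusted p = 0.955). It was 0.22 without S452A library 3 and 1.03 without S452A library 1, and did not pass in either case. Gzma differed by 0.51, Ifng by -0.21, Pdcd1, the inhibitory receptor PD-1, by -0.05, Tcf7, a factor of less differentiated T cells, by 0.12, Lag3 by 0.03 and Slamf6 by 0.15. The receptor-proximal kinase genes Lck and Zap70 differed by -0.29 and 0.14, and Csk, encoding a kinase that binds Pep, by -0.16. Cd8a differed by 0.14, Cd8b1 by 0.28, Cd3e by -0.15 and Cd4 by -0.09, and the chemokine receptor genes Cxcr3 and Cxcr6 by -0.46 and 0.14. Limma adjusted p was at least 0.952 for each gene of this panel that was tested. Leaving out 1 library could turn the sign for Ifng (-0.67 to 0.11), Pdcd1 (-0.31 to 0.27), Tcf7 (-0.11 to 0.31) and Cd8a (-0.38 to 0.59). It could also do so for Cd8b1 (-0.08 to 0.71), Cd3e (-0.56 to 0.14), Cd4 (-0.24 to 0.16), Lag3, Slamf6, Zap70, Cxcr6 and Cd69. The sign held for Gzma (0.30 to 0.80), Gzmb, Lck, Csk and Cxcr3. The interval for Cd8a ran from -1.37 to 1.64 on the log2 scale, so changes of more than 2-fold either way were not excluded for it. In at least 1 direction the same held for Cd8b1, Cd3e, Gzma, Gzmb, Ifng, Tnf, Pdcd1, Il7r, Lck, Zap70, Cxcr6 and Cxcr3. A small difference for these genes is therefore not evidence of no change (Pdcd1 -1.01 to 0.91, Zap70 -0.83 to 1.10). Panel genes at higher levels were Tnf (1163 ± 369 and 1576 ± 610 TPM), Il7r (129 ± 45.9 and 188 ± 75.6), Nr4a1 (122 ± 11.6 and 133 ± 33.6), Havcr2 (60.6 ± 6.59 and 71.5 ± 15.4), Cd69 (54.9 ± 11.3 and 53.9 ± 11.6) and Mki67 (32.5 ± 5.21 and 28.4 ± 6.11), with values as WT then S452A. Their log2 differences were 0.41, 0.52, 0.09, 0.22, -0.03 and -0.20 in that order. None of these genes passed a correlation test with the mean of the 8 T cell genes (Pearson r = -0.309, 0.0906, 0.607, 0.354, -0.119 and -0.592 in that order). In libraries with this content, their values cannot be credited to T cells. Prf1, Tox and Klrg1 fell below the expression filter and were not tested.

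Across the transcriptome, 1 of 13930 genes passed in S452A against WT, the predicted gene Gm36079, which was higher, and no gene was lower (limma adjusted p under 0.05). At an unadjusted p under 0.05 there were 660 genes, where chance alone would give about 697. The libraries of the genotypes did not overlap for 90 genes, or 0.646% of those tested, where chance gives 0.794%. With an exact Wilcoxon rank-sum test 0 genes passed, and 445 had an unadjusted p under 0.05. The 95% interval excluded a 2-fold change for 12108 of the tested genes (86.9%), on the log2(TPM + 1) scale, which understates changes of genes at low TPM.

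Gm36079 (ENSMUSG00000095029, chromosome 13, 120026439 to 120027011, GRCm38) was listed at 0 in all 5 WT libraries. In S452A libraries 1 to 5 it was at 16.79, 7.37, 4.69, 11.36 and 9.78 TPM (limma adjusted p = 0.000378). Its transcript is 99.8% identical over 573 nucleotides to Gm21188, a protein-coding gene at 120034605 to 120052194 on the same chromosome, so reads of these genes can be assigned to either. Gm21188 was at 66.7 ± 6.0 TPM in WT and 63.4 ± 9.33 in S452A (SD, n = 5, exact permutation p = 0.492). Their sum was at 66.7 ± 6.0 TPM in WT and 73.4 ± 6.73 in S452A, a log2 difference of 0.14 (SE 0.10, 95% interval -0.09 to 0.36, limma adjusted p = 0.952). Gm36079 took 5.65 to 23.7% of the sum in the S452A libraries and 0% in WT. With near-identical copies summed, an alternative added after the values were seen, 0 genes passed, with 657 at an unadjusted p under 0.05. Gm36079 added in full to the WT level would raise the sum by only 0.20 on the log2 scale, against the SE of 0.10. That is too little to pass over all genes, so the lost call does not tell shared reads from expression of Gm36079.

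**Figure D2:**
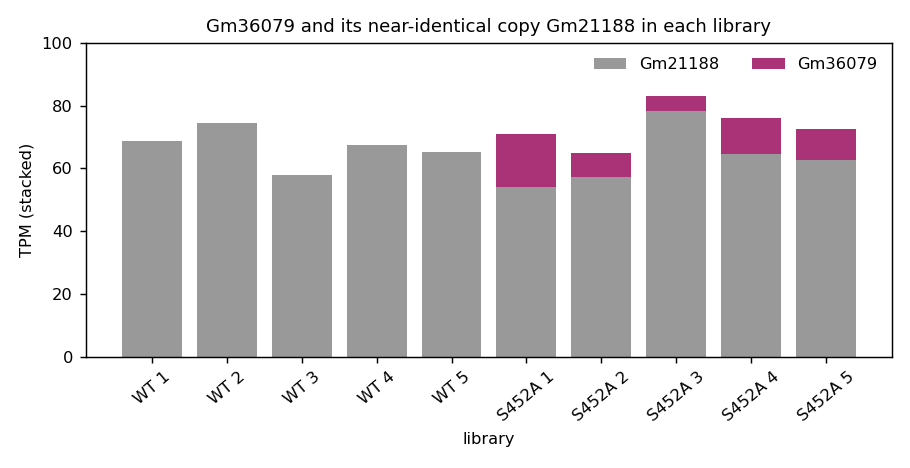
TPM of Gm21188 (grey) and Gm36079 (purple) as stacked bars in each of the 10 libraries. Gm36079 is listed at 0 in the 5 WT libraries and lies between 4.69 and 16.79 TPM in the 5 S452A libraries.

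The genes with the smallest unadjusted p after Gm36079 did not pass the limma adjustment, with an adjusted p of 0.847 for all 10 named here. On the higher side in S452A, Anxa1, the phospholipid-binding annexin A1, was at 344 ± 36.8 TPM in WT and 489 ± 63.6 in S452A (SD, n = 5), a log2 difference of 0.50 (SE 0.11). Cav2, a caveolin, differed by 0.73 (SE 0.15, 18.2 against 30.3 TPM), Rgcc, a cell cycle regulator, by 0.84 (SE 0.19), Ankrd13d by 1.12 (SE 0.25) and Exoc7, a subunit of the exocyst, by 0.67 (SE 0.15). On the lower side, mt-Atp6, a mitochondrially encoded subunit of ATP synthase, was at 3335 ± 562 TPM in WT and 1839 ± 478 in S452A, a log2 difference of -0.88 (SE 0.19). Summed with its nuclear copy Gm10925, which is 100% identical, mt-Atp6 differed by -0.39 (SE 0.22). Hps4, of a complex in lysosome-related organelle biogenesis, differed by -0.86 (SE 0.19), Mfap4, an extracellular matrix gene, by -1.42 (SE 0.33), Card6 by -0.83 (SE 0.19) and Bcl2l12 by -0.89 (SE 0.21).

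Of 33 gene lists tested, 6 passed camera with its preset correlation, and 0 passed with an estimated correlation (smallest adjusted p = 0.899) or with fry (smallest adjusted p = 0.953). By exact permutation of the list means 0 passed (adjusted p at least 0.974), but its smallest possible p, 0.00794, is too large for 1 list alone to pass over 33. The 13 mitochondrially encoded genes averaged 10.71 ± 0.44 in WT and 10.21 ± 0.35 in S452A as log2(TPM + 1) (SD, n = 5), with 13 of 13 members lower (mean difference -0.49, camera adjusted p = 1.46e-08, adjusted p = 0.899 with an estimated correlation, exact permutation p = 0.0873). Adjusted over the list alone, mt-Atp6 passed, and none did over all genes. mt-Nd2 differed by -0.40, mt-Nd4l by -0.86 and mt-Nd5 by -0.44, each with a limma adjusted p of 0.952. All 4 of these genes have nuclear copies of at least 95% identity, with which reads can be shared. Summed with their copies, mt-Atp6 differed by -0.39 (limma unadjusted p = 0.0912, so it passes no adjustment) and mt-Nd4l by -0.41, while mt-Nd2 and mt-Nd5 stayed at -0.40 and -0.44. Genes of fibroblasts and pericytes were lower in 19 of 23 members (mean difference -0.39, 3.74 ± 0.24 in WT and 3.35 ± 0.33 in S452A, SD, n = 5, camera adjusted p = 2.17e-06, adjusted p = 0.899 with an estimated correlation, exact permutation p = 0.0714). Its members Bgn, Postn and Col1a2, of the extracellular matrix, differed by -0.71, -0.65 and -0.76, and Acta2, a smooth muscle actin, by -0.58, and 0 members passed over all genes or adjusted over the list alone.

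**Figure D3:**
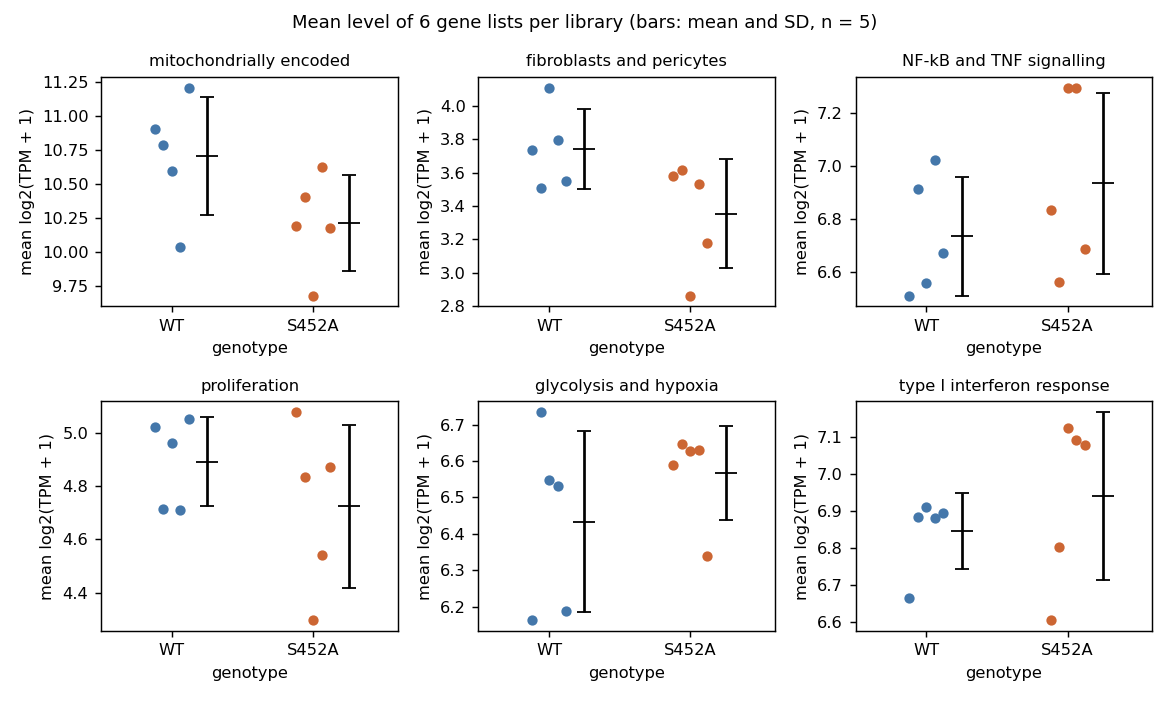
Mean log2(TPM + 1) of the members of 6 gene lists per library (points, 5 per genotype), with the mean and SD of each genotype as bars, each panel on its own axis. The mitochondrially encoded list averages 10.71 in WT and 10.21 in S452A, and the points of the genotypes overlap in each of the 6 panels.

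Genes of NF-kB and TNF signalling were higher in S452A in 23 of 23 members (mean difference 0.20, camera adjusted p = 0.00011, adjusted p = 0.899 with an estimated correlation). Members with the smallest p were Tnfaip3, a feedback inhibitor of the pathway, at 0.43, Nfkb1 at 0.33, Cflar at 0.40 and Nfkbia at 0.27. Proliferation genes were lower in 30 of 37 members (mean difference -0.17, camera adjusted p = 0.000316, adjusted p = 0.899 with an estimated correlation). The replication genes Mcm3, Mcm5 and Rrm2 were at -0.37, -0.41 and -0.46 and the mitotic kinase gene Aurkb at -0.66 (-0.38 without S452A library 3). Genes of glycolysis and hypoxia were higher in 24 of 27 entries (mean difference 0.13, camera adjusted p = 0.0026, adjusted p = 0.899 with an estimated correlation). They include Vegfa at 0.38, Bnip3 at 0.38 and, in the opposite direction, the glucose transporter gene Slc2a3 at -0.44. Aldoa has 2 annotated genes in this list; that at 1104 ± 337 TPM in WT and 1215 ± 154 in S452A differed by 0.18, and a neighbour under 2 TPM on average by 0.58. Type I interferon response genes were higher in 24 of 39 members (mean difference 0.09, camera adjusted p = 0.0256, adjusted p = 0.899 with an estimated correlation), among them Ifit1 at 0.49, Ifi209 at 0.35, Ifi203 at 0.33 and Slfn5 at 0.31. No member of these 4 lists passed over all genes or adjusted over the list alone. The number of lists passing was 3 without S452A library 3 and 19 without S452A library 1, and 6 with all libraries. The NF-kB, proliferation and interferon lists did not pass without S452A library 3 (adjusted p = 0.086, 0.179 and 0.575). The interferon list also did not pass without WT library 1, S452A library 4 or S452A library 5 (0.202, 0.133 and 0.533), and the glycolysis and hypoxia list without WT library 1 or 5 (0.202 and 0.195).

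The other 27 lists did not pass camera, with adjusted p from 0.102 to 0.910, and 0 of their members passed over all genes. Without S452A library 1, however, 13 of them passed at the preset correlation. Among these were the lists of CD8 T cell identity (camera adjusted p = 0.0242), Ptpn22 partners and substrates (0.0424), cytotoxic effector genes (0.00629), inhibitory receptors and exhaustion (0.0242), progenitor, naive and memory genes (0.0242) and early T cell receptor activation (0.0242), all toward higher in S452A. In that library the 8 T cell genes had a mean log2(TPM + 1) of 1.28, against 2.14 to 4.02 in the other S452A libraries. WT libraries 2 and 5 were also low, at 1.16 and 1.66, and stayed in that fit. Leaving out S452A library 1 thus removed a library poor in T cell transcripts from the S452A side only. The cytotoxic effector list also passed without WT library 1 or S452A library 4 (0.0327 and 0.0182). These calls rest on the preset correlation of 0.01, and an estimated correlation was run only with all libraries. There it was 0.689 for CD8 T cell identity (camera adjusted p = 0.963) and 0.310 for cytotoxic effector genes (0.899). Among lists of T cell state, mean log2 differences were 0.02 for CD8 T cell identity, 0.18 for cytotoxic effector genes, 0.06 for inhibitory receptors and exhaustion, 0.07 for progenitor, naive and memory genes, 0.05 for tissue residency, 0.08 for early T cell receptor activation and 0.05 for Ptpn22 partners and substrates. They were 0.06 for cytokine receptor and JAK-STAT genes, 0.06 for chemokines and their receptors, 0.01 for interferon gamma response and MHC class I, and -0.01 for apoptosis regulators. Metabolic and stress lists differed by -0.05 (nuclear-encoded oxidative phosphorylation), -0.12 (cholesterol and fatty acid synthesis), -0.04 (cytosolic ribosomal proteins), -0.01 (unfolded protein response), 0.02 (immediate early genes) and -0.02 (histones). The oxidative phosphorylation list passed camera, toward lower, without WT library 2 or 4 or S452A library 1, 2 or 5. It also passed with quantile normalization (adjusted p = 0.00235), a mean filter of 5 TPM (0.0457) or rescaling without mitochondrial and other genes (0.0473). The ribosomal list passed, toward lower, without WT library 2 or S452A library 1, 2 or 5, and with quantile normalization (0.00121). For other cell types the differences were 0.05 (macrophages and monocytes), 0.08 (dendritic cells), 0.17 (neutrophils), -0.05 (natural killer cells), -0.08 (CD4 and regulatory T cells), -0.28 (B and plasma cells), -0.13 (endothelial cells), -0.11 (epithelial and carcinoma cells), -0.07 (erythroid cells) and 0.04 (mast cells and basophils). Neutrophil genes passed camera, toward higher, without WT library 4 or S452A library 1 or 5 (adjusted p = 0.00504, 0.0242 and 0.0296). They also passed with a mean filter of 5 TPM (0.0363). Dendritic cell genes passed, toward higher, without S452A library 4 (0.0131). B and plasma cell genes passed, toward lower, without S452A library 5 (0.0209). The median had the opposite sign to the mean for histones (0.07), mast cells (-0.02), apoptosis regulators (0.03) and, near 0, immediate early genes, and the direction given by camera was opposite to the mean for histones, erythroid cells and apoptosis regulators. Adjusted over the list alone, 1 erythroid member passed, Car2, a carbonic anhydrase gene singled out after its values were seen, at 0.542 ± 0.132 TPM in WT and 1.6 ± 0.279 in S452A (limma adjusted p = 0.871 over all genes).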

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

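Chosen only after the result was seen were the tests on macrophage and T cell genes, on nuclear copies and Gm21188, on the sequence variant, and the counts of splits for genes and for lists; the GC test and the splits for the mitochondrial list were set before their values were seen.

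Macrophage transcripts stood far above T cell transcripts in 10 of 10 libraries labelled CD8+ T cells, although the labels describe a sort for CD8, which macrophages should not pass; 29 of the 36 genes in the macrophage list averaged at least 100 TPM, and 1 of the 36 is also in another list. Libraries made mainly of T cell RNA with some macrophage RNA are argued against, since the median of the 8 T cell genes reached at most percentile 55.4 of the tested genes. Dendritic cells that carry CD8 alpha are argued against by the median of Xcr1, Clec9a and Flt3, at most 1.64 TPM, and genotype by the presence of the pattern in 5 of 5 libraries of each. A sort that recovered mostly macrophages, and macrophage libraries placed under these names, cannot be told apart. Both predict the macrophage genes above the T cell genes in each library (by at least 6.08 on the log2 scale here, for the sets of 8). Which of these may hold stays open.

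The 13 mitochondrially encoded genes averaged lower in S452A, by -0.49 on the log2 scale (SE 0.25, exact permutation p = 0.0873, camera adjusted p = 0.899 with an estimated correlation). Reads shared with nuclear copies are argued against as the whole cause, since the list summed with its copies still differed by -0.42 (SE 0.21). Its exact permutation p stayed at 0.0873, and its camera adjusted p was 3.03e-09 at the preset correlation. The sum thus speaks to the size of the difference and does not establish the difference itself. mt-Atp6 alone moved from -0.88 to -0.39. GC content is argued against as far as the trend over nuclear genes reaches, which gave 0.0349 at the GC of these genes, the opposite direction. Only 140 of the 13914 nuclear genes used lie at or below that GC, so the trend was read near the edge of its data. Chance could not be excluded: 7 of 100 splits of the libraries gave as small a camera p for this list (4.44e-10, smallest of the other splits 2.1e-21), and 84 of 100 gave at least 6 lists past the threshold, with 23 the highest other count; the estimated correlation of genes within this list was 0.614, against the preset 0.01. Genotype thus stays open and untested beyond these values.

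Gm36079 was listed at 0 in the 5 WT libraries and above 0 in the 5 S452A libraries. Reads shared with Gm21188 and true expression of Gm36079 cannot be told apart, because the log2 difference of the sum, 0.14 (95% interval -0.09 to 0.36), covers both 0 and the 0.20 that Gm36079 would add to the WT level. A sequence variant between the mouse lines that moves reads from one copy to the other could give the share of at least 5.65% in each S452A library, but the gene was chosen for this separation and the table holds no reads, so this stays open. Chance could not be excluded for the count of genes: 25 of 100 splits gave at least 1 gene, with 17 the highest other count, and what sets the count of that split was not tested. An effect of genotype on the locus stays open as well.

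In 8 of 186 groups of 5 values, for named genes and lists, 1 library stood far from the other 4, by a gap above 0.71 of the range; chance flags about 1 in 20 groups, here 9.3. Lag3 was at 4.70 TPM in S452A library 3, against 2.83 to 3.25 in the other S452A libraries. Csk was at 79.2 TPM in WT library 5, against 96.2 to 104 in the other WT libraries. Bnip3 was at 105 TPM in WT library 2, against 57.0 to 64.5. The type I interferon list averaged 6.66 in WT library 1, against 6.88 to 6.91, and the glycolysis and hypoxia list 6.34 in S452A library 5, against 6.59 to 6.65. The dendritic cell list averaged 4.91 in S452A library 4, against 5.35 to 5.47. Neutrophil genes averaged 5.43 in WT library 4, against 4.70 to 4.90, and mast cell and basophil genes 1.95 in WT library 2, against 2.60 to 2.85.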

How the results depend on the processing

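The alternatives with the T cell gene mean as a covariate and with near-identical copies summed were chosen after seeing the data. Genes changed numbered 1 with all libraries and 1 to 1 when each library was left out. The count was 0 with a mean filter of 5 TPM, which removes Gm36079 (455 genes at an unadjusted p under 0.05). It was 0 with the exact Wilcoxon rank-sum test (445 genes). The smallest p of that test, 0.00794, is too large to pass over 13930 genes when only 90 genes separate fully. It was also 0 with near-identical copies summed (657 genes). There, full expression of Gm36079 would raise the sum by only 0.20 (SE 0.10), too little to pass over all genes. Lists past the threshold numbered 6, and 3 (without S452A library 3) to 19 (without S452A library 1) when each library was left out, 0 with an estimated correlation and 0 with fry; the cause was not tested for the left-out libraries. The mitochondrial and fibroblast lists passed camera in each of the 10 fits that left out a library. Other settings gave 5 to 8 lists; the interferon list did not pass with quantile normalization, the macrophage covariate or the T cell covariate (adjusted p = 0.185, 0.0819 and 0.0746). Robust moderation does not enter the list test and gave no value there. The Ptpn22 difference was 0.29, between 0.16 and 0.39 when each library was left out, and passed under none of the alternatives run. With the mouse number as a replicate block, 1 gene and 6 lists passed and the Ptpn22 difference was 0.29. Mice with the same number did not deviate together (correlations -0.00262, -0.15, -0.14, 0.07 and -0.04). In no pair of the same number was each library the best match of the other, and the block changed none of these counts.

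Of 1325 values of named genes under alternatives, 1323 kept their side of the threshold, 2 lost it (Gm36079 in the Wilcoxon test and summed with its copy), and 1288 kept the sign; sign changes of genes that passed in neither fit were not counted as reversals, and no called value reversed. For the 6 lists that passed, 120 values under alternatives stayed past the threshold and 23 did not, and 31 values of other lists passed it under an alternative. The median log2 difference of all genes lay between -0.0334 and -0.000693 in every setting. Depth is unknown, so what it limits could not be computed.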

Other observations

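All tests in this part were chosen after the library values had been seen.

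Although low, part of the T cell transcripts varied together between the 10 libraries. Against the mean of the 8 T cell genes, Pdcd1 had Pearson r = 0.962 (permutation p = 4e-05, adjusted p = 0.0006) and Spearman rho = 0.927 (permutation p = 0.00028, adjusted p = 0.00224), and r = 0.933 without the 2 libraries farthest from the median. In a family of 24 relations, 9 of the 23 panel genes outside the 8 had a positive Pearson correlation past the adjusted permutation p of 0.05, and the same 9 passed by Spearman: Pdcd1, Cxcr6, Gzmb, Tcf7, Tox, Prf1, Ifng, Lck and Zap70. Their r was 0.870 to 0.962 (adjusted p at most 0.00523), rho 0.806 to 0.952 (adjusted p at most 0.0199), r without the 2 farthest libraries 0.765 to 0.933, and r within genotype 0.871 to 0.964. The other 14 panel genes did not pass. Among them were genes at low levels, Klrg1 (r = 0.561, adjusted p = 0.166), Lag3 (0.553, 0.172), Gzma (0.531, 0.189), Cxcr3 (0.477, 0.246), Slamf6 (-0.280, 0.516) and Cd4 (-0.0309, 0.935), and Ptpn22 (0.464, 0.250). The others were Csk r = 0.677 (adjusted p = 0.0839), Nr4a1 0.607 (0.137), Mki67 -0.592 (0.137), Tnf -0.309 (0.490), Cd69 -0.119 (0.842), Il7r 0.0906 (0.878) and Havcr2 0.354 (0.423). The macrophage and monocyte list did not pass either (r = -0.0527, adjusted p = 0.920). These 9 genes are consistent with a T cell share that differs between libraries, a hypothesis found and tested on the same data; the cell counts behind it are not given in the sources used here.

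With the T cell gene mean as a covariate, 0 of 407 genes of the lists fixed for T cells, leaving out those 8, passed in limma. Of the 407, 12 had an unadjusted p under 0.05 (smallest adjusted p over these genes = 0.814). These lists include general programmes not particular to T cells, such as nuclear-encoded oxidative phosphorylation (59 tested genes), type I interferon response (39) and proliferation (37). Gzmb then differed by 0.49 (SE 0.22, limma adjusted p = 0.955). The 95% interval excluded a 2-fold change for 377 of the 407 genes (92.6%), a share that covers the general programmes as well as T cell genes. A genotype difference within the T cells could still be hidden, because the 8 T cell genes had a median of 1.26 to 15.6 TPM per library, where the pseudocount and the RNA of other cells can set these intervals. The requirement of a median of at least 20 TPM for excluding such a difference was added to the test after these intervals had been seen.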
